A study of Mus musculus with 36 samples.

How the data were processed

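ChIP-seq was done on primary mouse aortic smooth muscle cells, wild type or CSE knockout, all given 1 µM angiotensin II for 24 hours. The 36 samples comprise 18 immunoprecipitated and 18 input libraries, 3 per group. The labels call them separate samples but do not say whether they come from separate animals or cultures. Per the labels' protocols, libraries were amplified by PCR and sequenced on a HiSeq 2500. The submitters' processing notes name CASAVA 1.4 and the build mm9, and the aligner, peak caller and differential test are not given in the sources used here. Gene positions in the tables overlapped those of the RefSeq table of assembly GRCm38.p6 for 99.7% of 4986 matched symbols (H3K9ac), 99.6% of 2776 (H3K9me3) and 100% of 432 (H3K4me3). This check used gene positions only, and the build of the peak positions was not tested. Peak coordinates are printed as the authors give them and taken to be GRCm38, like the gene positions.

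The deposited tables hold 1 row per selected peak, with its annotation to a gene and its distance to a transcription start site. For H3K9ac and H3K9me3, per the file headers, the authors give the log2 mean normalised reads over all, knockout and wild-type libraries, a log2 fold change, a p-value and an FDR. How the authors normalised is not given in the sources used here. The log2 fold change equalled the difference of both group values within 0.01. The smallest absolute log2 fold change was 0.54 for H3K9ac and 1.71 for H3K9me3. The H3K4me3 table has none of these columns, so its tests of direction could not be made. Per-sample values were not analysed here, so the tests planned for counts or normalised values were replaced by counts of the authors' calls, as planned for that case. The p-values of the authors measure the spread between their samples, which may be technical.

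The tables analysed here list no peak with a p under 0.0001. If the deposited FDR is p times the number of tests over the rank, the listed H3K9ac p-values and FDRs imply 59000 tested peaks and 959 peaks ranked before the first listed one. That would make 9074 peaks with p under 0.05, or 15.4% of those tested. For H3K9me3 all 4559 peaks with a log2 signal under 3.6 have an FDR of 1. Among the other 815, the same arithmetic could be fitted only to the 117 with an FDR below 1. It gives 56617 tested, 31 unlisted and 1.49% with p under 0.05, below the 5% that chance gives. This share leaves out the 4559 peaks and takes the tested peaks to be those of higher signal only. It describes the cut at 0.05 alone, and the number of smallest p was not compared with chance. On simulated data the arithmetic was wrong by at most 0.643 unlisted peaks for H3K9ac and 6.40 for H3K9me3. The simulations had the FDR formula and the cut at 0.0001 built in, and no signal limit. Their errors are therefore not those of the 959 and the 31.

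Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and bedtools 2.31.1 for overlaps of at least 1 bp. Higher and lower peaks were compared by 2-sided Fisher's exact tests: promoter against other annotation, each of 20 chromosomes against the rest, and each of 32 gene lists against all other genes of the same table. Adjustment was by Benjamini-Hochberg within each family, over 2 marks for annotation because H3K4me3 has no direction. Odds ratios are sample values with exact 95% intervals. Overlaps were set against 1000 circular shifts of peaks within chromosomes (2-sided permutation test). Each gene took its promoter peak of smallest p. H3K4me3 promoter genes were counted per protein-coding gene of the RefSeq table, which matched 367 of 402. The functions were tested on simulated data: the chromosome test, on H3K9ac with 8115 peaks, called 100% of the changed and 3.24% of the unchanged chromosomes. Directions there were drawn independently for each peak, without runs of neighbouring peaks in 1 direction. The 3.24% is therefore not the rate of false calls in these data.

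The gene lists, most tests, most alternatives and the rule for named genes were fixed before the data were examined. The H3K4me3 test per protein-coding gene was not among the fixed tests. Neither were the tests of H3K9ac direction at H3K4me3 peaks or genes. They stand in for planned tests of direction, which H3K4me3 does not allow. The rule takes, per mark and direction, the 10 genes of smallest p among promoter peaks, ties going to the larger fold, leaving out predicted genes named by a number, and up to 4 examples per list. Genes outside it were chosen after their values were seen. Alternatives tried were stricter p, FDR, fold, signal, autosomes, 1 call per gene, other promoter definitions and other overlap rules.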

Results

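Primary aortic smooth muscle cells from wild-type C57BL/6N mice and from mice with a global knockout of cystathionine gamma-lyase (CSE, encoded by Cth), an enzyme that makes hydrogen sulfide, were studied after 24 hours with 1 µM angiotensin II, a vasoconstrictor peptide. Chromatin immunoprecipitation with sequencing (ChIP-seq) was done for 3 histone marks: H3K9ac and H3K4me3, found at active promoters, and H3K9me3, found in heterochromatin. The 36 samples formed 12 groups of 3 (each mark, immunoprecipitated or input chromatin, knockout or wild type). The values used here are the authors' comparison of knockout with wild type for each mark, with no value per sample, so the depth of each library is unknown and no spread between replicates could be computed. Each table lists only peaks the authors had selected, at a p of 0.05 by the file's title, and the counts below therefore describe how selected peaks split, not how many of all peaks differed. Tests across peaks or genes compare lists, and neighbouring peaks are not independent replicates.

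The H3K9ac comparison asked where acetylation at this residue differed between the knockout and wild-type cells. Most of its listed peaks were lower in the knockout: 6265 of 8115 peaks, or 77.2% (95% exact binomial interval 76.3 to 78.1%, which covers counting error only), against 1850 higher peaks. This split can depend on how the libraries were normalised, which is not given, and no other normalisation was run. The median higher peak was 2.50-fold higher and the median lower peak 2.19-fold lower in the authors' deposited table. At an FDR under 0.05 in that deposited table, the authors' values left 1344 peaks, of which 1019 were lower and 325 higher. The table analysed here lists no peak with a p under 0.0001, so the peaks named below are the first of those listed, and this count and its split leave out any peak of smaller p (959 by the rank arithmetic), whose direction is unknown.

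Among promoter peaks with the smallest listed p, Npr3, which encodes the natriuretic peptide clearance receptor, was 15.7-fold lower in the authors' deposited table (chromosome 15, 11903660 to 11907557, FDR 0.00673), the largest fold among the 10 lower genes. Limch1 was 8.40-fold lower and Fkbp10, a collagen chaperone of the endoplasmic reticulum, 3.41-fold lower in the authors' deposited table. Socs2, a suppressor of cytokine signalling, was 3.23-fold lower and Igf1, insulin-like growth factor 1, 2.55-fold lower there, per the authors' deposited table. The others of the 10 were Tbc1d15, Tnni2 (troponin I of fast skeletal muscle), Daam2, Ppfibp1 and Npff, at 2.75-fold to 2.14-fold lower in the authors' deposited table. On the higher side, AW112010 was 12.5-fold higher in the authors' deposited table (chromosome 19, 11050836 to 11051241, FDR 0.00704). Zfp950 was 7.16-fold, Pak3 (a p21-activated kinase) 6.68-fold and Gstm1 (a glutathione S-transferase) 5.39-fold higher in the authors' deposited table. Man1a, Phldb3, Prr15, Lonrf3, Synpo (an actin-associated protein) and Gsto2 (another glutathione transferase) were 3.76-fold to 2.22-fold higher in the authors' deposited table. All 20 of these genes had an FDR under 0.05 in the authors' deposited table. Several of the largest folds rest on few reads in 1 genotype. Wild-type log2 signal was 1.01 at AW112010, 2.11 at Zfp950, 2.39 at Pak3 and 3.04 at Gstm1 in the authors' deposited table. Knockout log2 signal was 1.81 at Limch1 there, but 6.03 at Npr3.

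**Figure D1:**
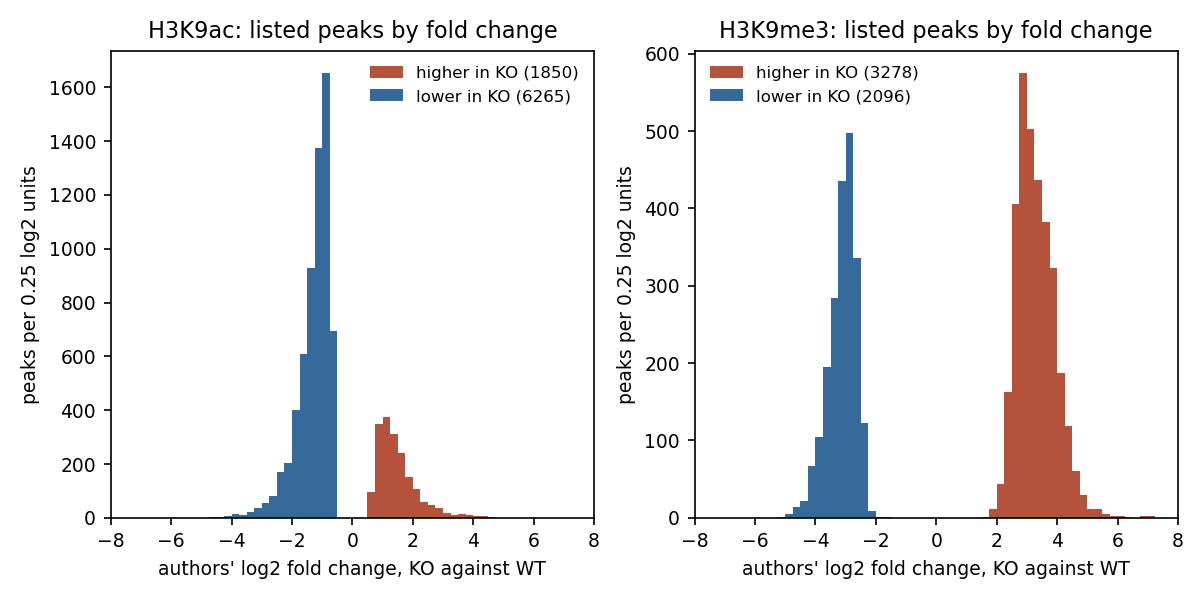
Histograms of the authors' log2 fold change (x axis, knockout against wild type) of the listed H3K9ac peaks (left) and H3K9me3 peaks (right), as peaks per bin on the y axis. H3K9ac holds 6265 lower and 1850 higher peaks, and H3K9me3 holds 2096 lower and 3278 higher peaks, with no peak near 0 because the tables were selected.

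Genes were given 1 call each, from the promoter peak of smallest p, which gave 668 higher and 2383 lower genes for H3K9ac. All 17 listed genes of the extracellular matrix list were lower, among them Ccn2 (2.36-fold), Col4a2 (7.46-fold), Fbln1 (2.97-fold) and Col3a1 (2.41-fold) in the authors' deposited table. The Col4a2 fold rests on few reads, with a knockout log2 signal of 1.86 in the authors' deposited table. Of the 17 matrix genes, 5 had an FDR under 0.05 in the authors' deposited table, and the rest are listed by unadjusted p only. Of the listed genes outside this list 78.0% were lower. The list's difference from them had a Fisher's exact p of 0.0333 (adjusted 0.297 over the lists), so it did not pass. With all peaks annotated to a gene, not only promoter peaks, the list had 3 higher and 21 lower genes (exact p 0.235). Of 10 listed contractile genes 8 were lower, including Ldb3 (2.50-fold) and Lmod1 (2.35-fold), while Smtn was 1.93-fold higher in the authors' deposited table. All 3 listed genes of the synthetic smooth muscle list were higher in the authors' deposited table: Vcam1 (2.35-fold), Ly6a (2.50-fold) and Spp1 (2.43-fold), with an exact p of 0.0105 (adjusted 0.297). With all annotated peaks this list had 6 higher and 3 lower genes (exact p 0.00847, adjusted 0.271). The inflammation list had 5 higher and 4 lower genes (exact p 0.0284, adjusted 0.297), with Ccl2 2.50-fold higher and Tnfrsf1a 2.13-fold lower in the authors' deposited table. The oxidative stress list had 4 higher and 3 lower genes (exact p 0.0452, adjusted 0.297), with Gstp1 2.41-fold higher and Gpx4 2.99-fold lower in the authors' deposited table. With all annotated peaks the inflammation list had 7 higher and 9 lower genes (exact p 0.0804) and the oxidative stress list 4 higher and 7 lower (exact p 0.313). The other cell types' markers were few: the leukocyte genes Cd14 (1.79-fold) and Aif1 (1.66-fold) and the endothelial gene Pecam1 (1.72-fold) were higher in the authors' deposited table. Both leukocyte genes were the whole of that list's calls (exact p 0.0479, adjusted 0.297; 2 higher and 2 lower with all annotated peaks, exact p 0.249), and the adipocyte gene Lipe was lower. Fibroblast markers gave 1 higher and 2 lower genes, and neural crest markers 1 higher and 1 lower.

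Chromatin enzyme genes were mostly lower, as were 78.0% of the other listed genes. Of 13 listed genes of the histone methylation list 12 were lower, including Tet1 (a DNA demethylase, 2.33-fold), Mecom (2.19-fold), Trim28 (2.04-fold) and Kdm4b (1.87-fold) in the authors' deposited table. All 5 listed histone acetylation genes were lower, with Kat8, an acetyltransferase, 3.51-fold and Brd2, an acetyl-lysine reader, 2.50-fold lower in the authors' deposited table. Neither list differed detectably from the other genes (exact p 0.321, adjusted 0.756, and exact p 0.592, adjusted 0.874). Of 16 canonical histone genes 15 were lower, of 54 microRNA genes 46 and of 39 zinc-finger genes 32. The angiotensin list had 7 lower genes and 1 higher, with Nox4, an NADPH oxidase, 1.99-fold lower in the authors' deposited table. Proteases and inhibitors gave 5 lower genes, Mmp2 (2.11-fold) and Serpine2 (2.17-fold) among them, and 3 higher genes, with Adamts9 2.81-fold higher in the authors' deposited table. The hydrogen sulfide list had Slc7a11, a cystine transporter, 1.79-fold higher and Mtrr 2.50-fold lower in the authors' deposited table. Human aneurysm risk genes gave 8 lower and 2 higher genes, and positional transcription factors 10 lower and 2 higher. Of the list genes named with a fold above, Gpx4, Cd14, Aif1, Pecam1, Nox4, Slc7a11 and Mtrr had an FDR over 0.05 in the authors' deposited table and are listed by unadjusted p only. Of the 31 lists with any H3K9ac call, 0 passed at an adjusted p of 0.05 by Fisher's exact test and 5 passed unadjusted.

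**Figure D2:**
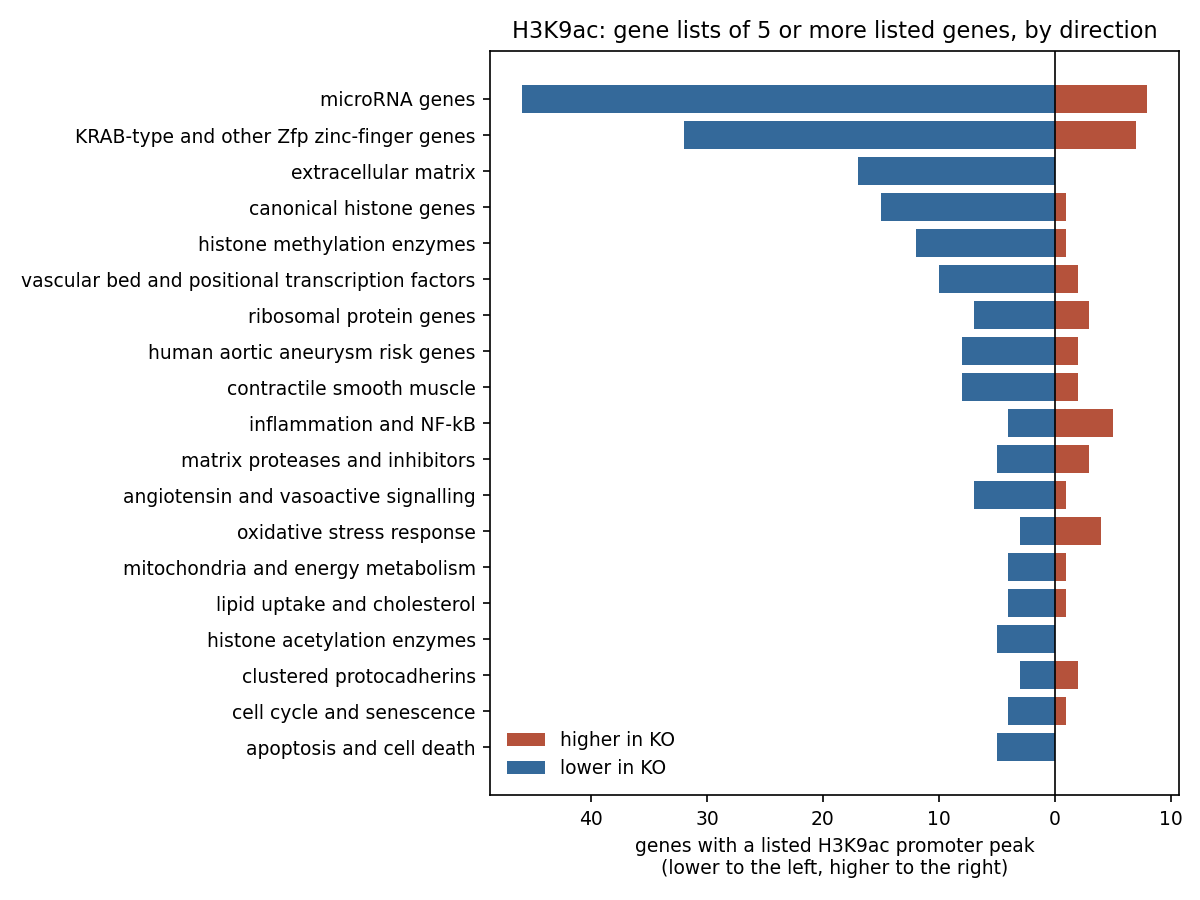
Number of genes with a listed H3K9ac promoter peak that were higher (right, red) or lower (left, blue) in the knockout, for each gene list with 5 or more such genes (y axis). All 17 extracellular matrix genes are on the lower side, and inflammation genes are 5 higher and 4 lower.

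The H3K9me3 comparison asked the same of heterochromatin. Of 5374 listed peaks 3278 were higher and 2096 lower in the knockout, or 39.0% lower (95% exact binomial interval 37.7 to 40.3%). That share depended on the threshold: 25.6% of listed peaks were lower at p under 0.01 and 13.5% at p under 0.001. It can also depend on the normalisation, which is not given. No listed peak reached an FDR under 0.05 in the authors' deposited table: 0 peaks, with a smallest FDR of 0.2, so none of the listed differences passed a corrected test and the peaks are given by their unadjusted p. Peaks with a p under 0.0001 are not listed in the table analysed here, and whether they passed is unknown. The rank arithmetic gives 31 among peaks with a log2 signal of 3.6 or more, and no number for those of lower signal. Signal was low, with a median of 6.68 normalised reads per library at a listed peak against 40.8 for H3K9ac, per the authors' deposited table. In 1030 peaks the wild-type value and in 547 the knockout value lay at the lowest level in the table, so those folds depend on that level. The promoter peaks of smallest p were Kcns3 (58.5-fold, FDR 0.220), H2-Q7 (34.3-fold), Dpp6 (33.4-fold), Sprr2a2 (39.4-fold) and Lonrf2 (72.5-fold), all higher in the authors' deposited table. Tle7, Pcsk5, Dlx2, Lmo1 and Gabrg3 followed, at 37.5-fold to 50.2-fold higher in the authors' deposited table. On the lower side were Tiam1 (29.0-fold), Insm2 (23.8-fold), Olfr773 (17.9-fold), Ass1 (21.4-fold) and Cyp2c53-ps (12.4-fold), each with an FDR of 1 in the authors' deposited table. Rdh16f2, AY702102, Pde3a, Tshz2 and Mapk4 completed them, at 13.7-fold to 9.06-fold lower in the authors' deposited table.

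The H3K9me3 promoter peaks covered 432 higher and 187 lower genes, too few for most lists to have many members, and depletion of a list was not tested. No contractile, matrix, protease, angiotensin or hydrogen sulfide list member had a listed promoter peak, while with all annotated peaks the matrix list had 3 higher and 3 lower genes (exact p 0.687). The synthetic list had only Olr1 (6.11-fold lower, FDR 1, in the authors' deposited table) and the inflammation list only Il33, with a log2 fold change of −3.58 in the authors' deposited table (FDR 1). Olfactory receptor genes had 14 higher and 7 lower calls, zinc-finger genes 4 higher and 5 lower, and microRNA genes 6 higher and 1 lower. Vomeronasal receptor genes had 2 higher and 6 lower calls (Fisher's exact p 0.0112, adjusted 0.101), which did not pass, and with all annotated peaks they had 30 higher and 21 lower (exact p 0.886).

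Higher and lower peaks differed in where they lay. Promoters made up 40.8% of higher and 46.2% of lower H3K9ac peaks (odds ratio 0.804, 95% interval 0.723 to 0.895, Fisher's exact adjusted p 4.70e-05). This difference did not pass with peaks of p under 0.01, where the odds ratio was 0.864 (exact adjusted p 0.0757). For H3K9me3, promoters made up 14.1% of higher and 9.54% of lower peaks (odds ratio 1.56, 95% interval 1.30 to 1.87, exact adjusted p 9.88e-07). The odds ratio was 2.42 with peaks of p under 0.01 (exact adjusted p 4.47e-05) and 2.27 with a start site within 1 kb (exact adjusted p 1.53e-10).

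The H3K4me3 table lists 469 peaks, of which 411, or 87.6%, were annotated to promoters, of 402 genes. It gives no fold change, p or direction for a peak, so none is reported. List members among its promoter genes were few: Bub1, Cdk6, Mcm2, Mdm2 and Sirt1 of the cell cycle list, and Bak1, Bax, Birc2 and Pmaip1 of the cell death list. Hox genes numbered 3 (Hoxa3, Hoxa4 and Hoxb13). Single members were Ccn1 (matrix), Mmp24 (proteases), Adra1d (angiotensin), Skil (TGF-beta) and Mat2a (transsulfuration and aneurysm risk), with Sirt1 also in the histone acetylation list, H3c8 (canonical histones) and Rps19 (ribosomal proteins). Zinc-finger genes had 7, and positional factors (Foxc2, Nkx2-3), microRNA genes and cytochrome P450 genes (Cyp26b1, Cyp4f17) 2 each, while the contractile, synthetic and inflammation lists had 0.

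Between marks, positions were compared first. Of the H3K9ac peaks, 71 overlapped a listed H3K4me3 peak by at least 1 bp, against 3.69 expected from 1000 circular shifts (permutation p 0.002, the smallest they can give). The shifts do not keep peaks at promoters, where 44.9% of H3K9ac and 87.6% of H3K4me3 peaks lay, so this excess does not separate shared changes from shared location. Of these 71 peaks 69 were lower, or 97.2%, against 77.0% of the other H3K9ac peaks (odds ratio 10.3, 95% interval 2.74 to 86.7, Fisher's exact p 5.11e-06). Chromosomes 6, 10 and 15 were rich in listed H3K4me3 peaks, and H3K9ac was lower more often there. Without them 36 peaks were lower and 2 higher (odds ratio 6.05, exact p 0.00235). This odds ratio lies within the interval of the full set. Whether part of the contrast goes with chromosome is therefore not settled. By gene, 91 of 99 genes with promoter calls in both tables had lower H3K9ac, or 91.9%, against 77.6% of other H3K9ac genes (odds ratio 3.28, exact p 2.97e-04). The gene comparison was not repeated without those chromosomes. H3K9ac and H3K9me3 overlapped at 4 peaks against 25.2 expected (permutation p 0.002), the promoters of Gal3st1, Ehd3, Rerg and Isyna1. Only 12.3% of H3K9me3 peaks lay at promoters, so the location of each mark alone can give such a deficit, which says nothing about the changes. It was not detectable with peaks of p under 0.01 (1 peak against 2.83 expected, permutation p 0.446). Of 28 genes with promoter calls in both, 17 had lower H3K9ac with higher H3K9me3, 3 the opposite, 5 both lower and 3 both higher (Fisher's exact p 0.311; Spearman rho −0.17 across genes, which are not replicates). H3K9me3 and H3K4me3 overlapped at 3 peaks against 1.80 expected (permutation p 0.545).

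Direction depended on the chromosome. For chromosome X 6.62% of H3K9ac peaks were higher (odds ratio 0.236 against the rest, Fisher's exact adjusted p 9.01e-07), and chromosome 3, which holds Cth, had 12.8% higher (odds ratio 0.481, exact adjusted p 2.93e-07). Chromosome Y had 1 listed H3K9ac peak and 32 H3K9me3 peaks, of which 25 were higher. The highest H3K9ac shares were on chromosomes 18 (63.2%, exact adjusted p 1.23e-40) and 4 (62.8%, exact adjusted p 8.57e-39), against 22.8% over the table. With neighbouring peaks of 1 direction within 100 kb merged, their odds ratios fell. They went from 6.24 to 3.33 on 18 (exact adjusted p 1.64e-11) and from 6.11 to 3.40 on 4 (exact adjusted p 2.51e-12). In all, 17 of 20 chromosomes passed at an adjusted p of 0.05 for H3K9ac and 14 for H3K9me3. H3K9me3 peaks were higher in 88.6% on chromosome 8 (exact adjusted p 3.50e-28) and 27.6% on chromosome 6 (exact adjusted p 7.69e-49), with 62.2% on chromosome 3 and 80.7% on X. Chromosome 6 held 88 of the 469 H3K4me3 peaks, and 6.48% of its protein-coding genes had one at the promoter against 1.43% elsewhere (odds ratio 4.77, 95% interval 3.61 to 6.23, exact adjusted p 3.26e-22). Chromosomes 10 (odds ratio 2.58, exact adjusted p 5.13e-06) and 15 (odds ratio 2.09, exact adjusted p 0.00386) also held more than the rest, and chromosomes 4, 9, 13 and X fewer.

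**Figure D3:**
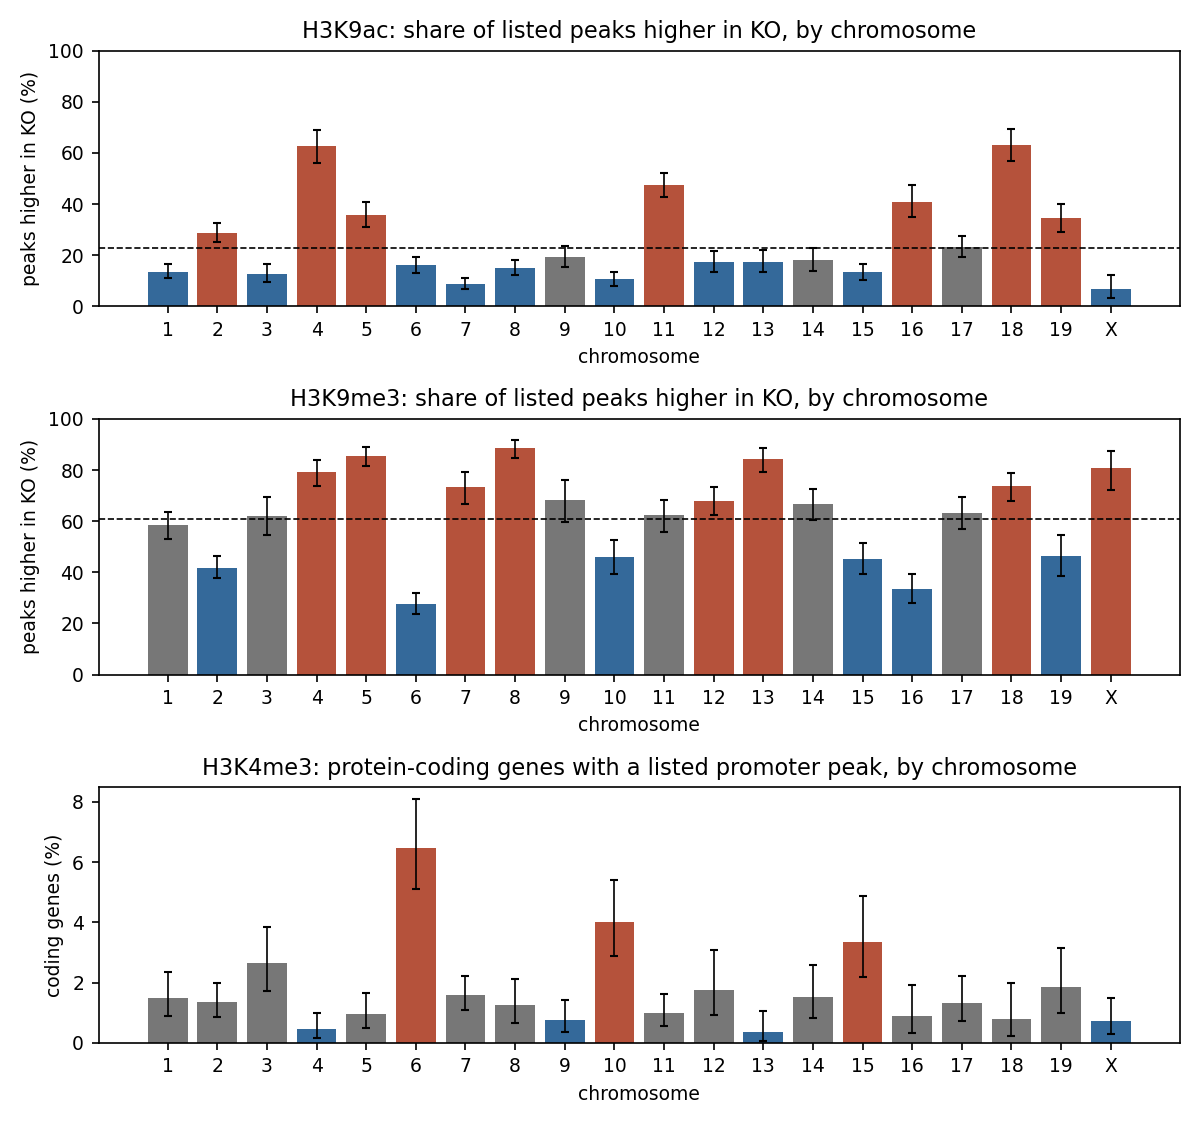
Percent of listed peaks higher in the knockout on each chromosome for H3K9ac (top) and H3K9me3 (middle), and percent of protein-coding genes with a listed H3K4me3 promoter peak (bottom). Error bars are 95% exact binomial intervals. Dashed lines, in the top and middle panels only, are the share over the whole table. Red and blue bars are chromosomes above and below the rest at an adjusted p of 0.05, and grey bars are the others. Chromosomes 4 and 18 reach 62.8% and 63.2% for H3K9ac, and chromosome 6 reaches 6.48% for H3K4me3.

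At Cth itself, 0 listed peaks of any of the 3 marks were annotated to the gene or lay within 10 kb of it, so the knockout was not checked at its own locus. No H3K9ac or H3K9me3 peak with a p under 0.0001 is listed. A strong difference at Cth in these marks could therefore have been left out. The nearest listed peak was an intronic H3K9me3 peak 40.6 kb away (chromosome 3, 157965681 to 157966060). It had a log2 fold change of 3.43 and an FDR of 1 in the authors' deposited table.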

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

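The tests of explanations in this part were chosen after the results were seen. The H3K9ac and H3K9me3 chromosome tests they start from were planned, while the H3K4me3 test per protein-coding gene was not. A signal appeared outside the nuclear chromosomes: the H3K9me3 table lists a peak on the mitochondrial chromosome (1 to 1047, at mt-Tf) with a log2 fold change of 6.41 in the authors' deposited table (FDR 0.560). Mitochondrial DNA carries no histones.

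Chromosome-wide direction is the first pattern. A copy number profile shared by the libraries of both marks is argued against as the whole cause by 8 chromosomes (2, 7, 8, 12, 13, 16, 19 and X) that passed in both marks in opposite directions (4 at p under 0.01, 7 at 2-fold, 5 after merging), while it stays open for the 6 (4, 5, 6, 10, 15 and 18) that passed in the same direction. Runs of neighbouring peaks are argued against as the whole cause, since 14 of 20 chromosomes still passed for H3K9ac after merging peaks within 100 kb. Whole-chromosome copy number in the H3K9ac cultures stays open: the shares higher in the start-side and end-side parts of each chromosome had a Spearman rho of 0.871 (permutation p 1.00e-05, the smallest they can give), 0.899 when split at the median peak, and for H3K9me3 0.890 and 0.811. The input libraries that could decide it were not analysed here, and an effect of genotype stays open, untested. Sex of the animals and the strain region around Cth, which the plan named for X, Y and the Cth chromosome, were also not tested.

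H3K4me3 peaks on chromosome 6 are the second pattern, the largest of 3 enriched chromosomes with 10 and 15; both other marks were also lower more often there than elsewhere, though H3K9me3 on 15 not at p under 0.01 (odds ratio 1.03) and H3K9ac on 6 no longer past the threshold after merging (0.779). The marks did not go together on every chromosome. H3K9ac was lower most often on chromosomes X and 7 (odds ratios 0.236 and 0.301). Neither had an excess of H3K4me3 promoter genes (0.412 and 0.921), and H3K9me3 was higher more often there (2.72 and 1.80). For chromosome 6, a larger number of genes is argued against by the odds ratio of 4.77 per protein-coding gene (95% interval 3.61 to 6.23). A different copy number of chromosome 6 may account for it, as both parts of the chromosome were enriched (odds ratios 4.70 and 4.81), and an effect of genotype is open, untested.

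The missing small p-values are the third pattern. That no peak reached a smaller p is argued against by the 959 H3K9ac ranks before the first listed peak. A step that left out rows at a p of 0.0001 is a candidate explanation, since listed p did not thin out above it: of 176 H3K9ac peaks with p between 0.0001 and 0.0002, 10.8% lay under 0.00011 (95% exact interval 6.63 to 16.3%), against 10% for an even spread. No biological explanation was tested, and where such a step took place is not known. The strongest H3K9ac differences would then be absent from every count and list above.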

How the results depend on the processing

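Merging of neighbours, removal of floor peaks, the subsets of H3K4me3-overlapping peaks, the alternatives for chromosomes opposite between marks and the term sizes were chosen after seeing the data. No paired analysis was possible because the tables give no value per sample. For the same reason the replicate block, other normalization and leaving out a replicate were not run, nor was any alternative that needs a p, fold or signal for H3K4me3. H3K9me3 had too few genes shared with H3K9ac at p under 0.01 for a gene-level test. The smaller counts below follow from fewer peaks being kept, and other causes were not tested.

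For H3K9ac, higher and lower peaks (percent lower) were 814 and 2585 (76.1%) at p under 0.01, 220 and 658 (74.9%) at p under 0.001 and 325 and 1019 (75.8%) at FDR under 0.05. These stricter sets lack the peaks with p under 0.0001 (959 by rank), whose direction is unknown, so their counts and percents describe the listed peaks only. At least 2-fold left 3988 lower (73.9%), leaving out the peaks of lowest signal gave 79.2% lower, 1 call per gene 75.8%, and merging 2860 lower (68.4%). For H3K9me3 they were 995 and 342 (25.6%) at p under 0.01, 96 and 15 (13.5%) at p under 0.001, and 0 and 0 at FDR under 0.05, which leaves no percent to give. These again describe listed peaks only (31 unlisted by rank among peaks with a log2 signal of 3.6 or more). Without the peaks of lowest signal 1397 were lower (34.6%), merging gave 41.6% and leaving out floor peaks 40.8%.

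With p under 0.01 the H3K9ac promoter odds ratio was 0.864, no longer past the threshold, and H3K9ac and H3K9me3 shared 1 peak, also no longer past it. H3K9me3 and H3K4me3 shared 3 peaks within 1 kb (3.82 expected) and 0 at p under 0.01 (0.419 expected), below expectation instead of above, with neither past the threshold. On chromosome 15 the H3K9me3 odds ratio turned to 1.03 at p under 0.01. No gene list passed the adjusted threshold under any setting. Unadjusted, H3K9ac lists past it were 1 with all annotated peaks, 1 at p under 0.01 and 3 at 2-fold, and H3K9me3 lists were 2 with all annotated peaks and 0 at p under 0.01. The lower H3K9ac at H3K4me3 peaks kept its direction and call in all 7 alternatives, with odds ratios from 6.04 to 15.4. Pathway terms past the adjusted threshold were 2 with at least 10 genes per term, against 0 with at least 5, 15 or 20, and both were too small to be tested at 15 or 20.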

Other observations

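The genes and terms in this part were chosen after their values were seen. The genes with the most lower H3K9ac peaks were Tns1 (24), Mical2 (15), Trio (13), Fbln2 (12), Myh9 (11), Osbpl3 (11, with 1 higher), Actn4 (10), Cemip (10), Foxp1 (10, with 2 higher) and Actn1 (9, with 1 higher). No shared function was tested. Median folds were 1.91-fold lower at Tns1 and 2.05-fold lower at Fbln2 in the authors' deposited table. On the higher side Tnfrsf1b, Tns4, Galk2 and Susd6 had 6 peaks each, and Hif1a, a hypoxia-responsive transcription factor, had 4, with a median of 3.84-fold in the authors' deposited table.

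Some H3K9me3 peaks lay in long runs of 1 direction, picked here by their number of peaks. On chromosome 2, 119 lower peaks ran from 169344033 to 169979065, 63 of them annotated to Tshz2, with a median log2 fold change of −3.18 in the authors' deposited table. On chromosome 8, 43 higher peaks spanned 355 kb around Zfp423, with a median log2 fold change of 3.40 in the authors' deposited table. Another 43 higher peaks spanned 244 kb on chromosome 5. The 25 H3K9me3 peaks of highest signal were all higher in the knockout, with FDRs from 0.568 to 1 in the authors' deposited table. Several were annotated to pseudogenes or predicted genes, and whether they lie in repeated or multi-copy sequence was not tested, so they are not taken as a genotype difference.

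Terms of the authors' annotation were compared between higher and lower H3K9ac promoter genes by Fisher's exact test. With at least 15 genes per term, the setting run first, 0 of 353 gene ontology terms and 0 of 128 pathways passed at an adjusted p of 0.05, while 27 and 6 passed unadjusted. Xenobiotic metabolism by cytochrome P450, with 9 higher and 4 lower genes (Gstm1, Gstp1 and Ugt1a6a among the higher), passed with at least 10 genes per term (exact adjusted p 0.0434) and not with at least 5 (exact adjusted p 0.0596), and was too small to be tested at 15 or 20. Drug metabolism by cytochrome P450, with 8 higher and 3 lower genes, had the same adjusted p at both sizes and was also too small for the others, and 0 gene ontology terms passed at any of the 4 sizes. These calls rest on the minimum size and are not treated as findings.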
